A study of Mus musculus with 6 samples.

How the data were processed

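The data came from 6 libraries of A2 lox.Cre Bcl6 mouse ES cells, a line with a tetracycline-inducible Bcl6 transgene, differentiated into cortical progenitors. Per the labels, 3 libraries were precipitated with an antibody to Bcl6 and 3 were input DNA, and the series' design states that the libraries were pooled for analysis. Sequencing was on a Genome Analyzer IIx, per the labels' protocols. The submitters' processing notes name Bowtie and the mm10 build, and no Bowtie version is given in the sources used here.

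There were 2 processed files, a table of peaks and a list that ties each peak to genes. Peaks were called with MACS 1.4.2, per the file headers, on the pooled ChIP against the pooled input, with a p-value cutoff of 1e-05, a band width of 300 bp, a tag size of 26 bp, a fragment size of 188 bp and at most 1 tag per position. The tag counts per peak are deposited as raw counts of pooled ChIP tags. The fold enrichment is a ratio of ChIP over the local background from the input that the authors' peak caller computed, with the background read over 1000 and 10000 bp. The p-value score was deposited by the authors as −10 log10 of the peak caller's p-value. A spreadsheet had overwritten the name of its column in the authors' table, and it was identified from the order of the columns and from its minimum of 50.03, which is the stated cutoff on this scale. The empirical FDR is a percent in the authors' table. How it was computed is not given in the sources used here, and this peak caller is known to obtain it by exchanging ChIP and input. The gene list was deposited as the output of GREAT 3.0.0 for mm10, per the file headers, with basal domains of 5000 bp upstream and 1000 bp downstream of each TSS extended by up to 1000000 bp. It gives the signed distance of each peak centre to the TSS.

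The gene list numbers the peaks in the order of the peak table. This was checked on 5358 peak and gene pairs by placing the TSS from the peak centre and the distance. The median gap to an end of the named gene was 45 bp, and 82.4% of the pairs were within 1000 bp. Upstream and downstream of a TSS refer to the TSS of the authors' list, which can lie inside the gene body. Symbols were matched to a RefSeq gene table of the GRCm38.p6 assembly, the same build as mm10, by current symbol (5358 pairs) or by a unique older symbol (358 pairs). This matched 98.5% of 5801 pairs, and 82 pairs without a match and 3 on another chromosome were kept only for distances. Coordinates are those of the authors' table.

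The gene table gives no strand and no genome sequence was used here. A planned test for the Bcl6 motif in the peaks was therefore not run. The planned promoter test named the peak summit, but the distance to a TSS was known only for the peak centre, so the observed share uses the centre, and the summit against both gene ends was added as an alternative. Random placements drew each peak 10000 times with its width on its chromosome between the first and the last protein-coding gene, without masking assembly gaps, and counted placements within 1 kb of either end of a protein-coding gene. The peak on unplaced sequence was left out of the placements, which leaves 3877. For the gene lists, observed and placed peaks were each assigned to the protein-coding gene with the nearest end. Observed counts in that alternative therefore differ from those of the main test, which uses the authors' gene list.

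Gene lists were tested with Fisher's exact test, two-sided, against all 21887 protein-coding genes, with Benjamini-Hochberg adjustment over the 16 lists and exact 95% binomial intervals. The intervals cover counting of genes only. Fold enrichment at promoter and other peaks was compared with a Mann-Whitney test by 100000 permutations, and 6 relations between peak values with Spearman's rho and 10000 permutations. All these tests run over genes or peaks of a single pooled data set, and genes and peaks are not independent replicates. No replicate could be left out.

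On simulated data for the list test over 21887 genes, lists planted with a peak in 60% of their members were called in 100% of 200 tests, and lists left at chance in 0.643% of 1400. In the logistic model with domain length, planted lists were called in 100% of 20 tests, and its rate for lists at chance was not computed. Genes with a peak were drawn evenly in these simulations. The rates therefore do not cover bias from domain length or from peaks shared by neighbouring genes. For the placement test, 3.30% of 3877 random positions fell within 1 kb of a gene end, and 41.5% when 40% of them were moved onto gene ends.

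The alternatives fixed before the data were examined were only the peaks with a score at or above the median, an FDR of at most 5%, no chromosome Y or unplaced sequence, promoter windows of 2 and 5 kb, any overlap, all annotated genes, assignment to the nearest TSS or within 5 kb and the gene body, a domain length covariate, random placements for the lists, and the score in place of the fold. Others were chosen after seeing the data. They were peaks at most 2 kb wide, peaks within 1 kb or over 5 kb from a TSS, a background without receptor and keratin families, and the summit. The genes named were fixed by rule before the data were examined. They are Bcl6, Hes5, Hes1, Ccnd1 and Ccnd2, the 10 genes with the highest fold, the 5 with the most peaks, and in each list up to 4 with the highest fold at their strongest peak, without predicted gene models among the highest. This gave 75 genes, some of which are not reported here. Python 3.11.15 was used with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.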

Results

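Bcl6, a zinc finger transcriptional repressor best known from germinal centre B cells, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in cortical progenitors grown from mouse embryonic stem (ES) cells. The ES line carried a Bcl6 transgene under a doxycycline-inducible promoter, and Bcl6 was induced for 24 h with 1 µg/ml doxycycline at differentiation day 12. The study had 2 groups, 3 libraries precipitated with an antibody to Bcl6 and 3 libraries of input DNA. The authors pooled the libraries of each group before calling peaks, so no value below has a replicate error, and every peak value is the authors' own for the pooled data. The pooled ChIP held 56836596 tags, of which 11718276 (20.6%) stayed after the peak caller kept 1 tag per position. The pooled input held 12808138 tags, of which 5048582 (39.4%) stayed. Cells without induction were not analysed here, so induced and endogenous Bcl6 are not separated.

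The screen asked where Bcl6 sat in the progenitor genome. It gave 3878 peaks that together covered 6.56 Mb of the mm10 genome and held 2.54% of the retained ChIP tags. Klf9, which encodes a Krüppel-like transcription factor, had the peak with the highest enrichment over input, at 269-fold on chromosome 19 from 23075226 to 23076695, 65.3 kb upstream of its transcription start site (TSS). Trpm3, a cation channel gene whose TSS lay 937 kb away, was listed for the same peak. Socs2, a feedback inhibitor of JAK/STAT signalling, had the most significant peak of the data set, with a p-value score (−10 log10 p) of 2712, 984 tags and 171-fold enrichment 14 bp from its TSS.

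Other genes next to strong sites lay far from them. A peak of 198-fold on chromosome 13 was listed for Asb13, at 78.8 kb, and for Calml3, at 91.5 kb. A peak of 193-fold on chromosome 9 was 152 kb upstream of Glce and 59.5 kb downstream of the TSS of Spesp1. Zbtb20, which encodes a BTB and zinc finger repressor of the developing cortex and hippocampus, had a peak of 193-fold 137 kb upstream, and the same peak lay 430 kb upstream of the growth cone gene Gap43. Over all peaks the median enrichment was 21.3-fold (range 7.98 to 269), the median tag count was 58 (20 to 1158) and the median width was 1405 bp (356 to 13470).

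Some genes collected several peaks. Tgif1, which encodes a homeodomain corepressor of TGF-beta signalling, had 9, the most of any gene. They spread from 65.2 kb upstream to 113 kb downstream of its TSS, and none exceeded 19.8-fold. Klf9, Rere, Zmiz1 and Zmynd8 had 6 each. The second peak of Klf9 lay 46.1 kb upstream at 53.2-fold, and its promoter peak reached 25.4-fold. In all, 3611 genes had 1 peak and 237 had 3 or more.

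The genes fixed for reporting whatever their result were Bcl6, Hes1, Hes5, Ccnd1 and Ccnd2. Bcl6 itself carried a peak of 64.8-fold over its own TSS, on chromosome 16 from 23988367 to 23989268, with 103 tags and a score of 307. The Notch effector Hes1 had weaker peaks on both sides of its TSS, of 13.0-fold 1219 bp upstream and 15.1-fold 1449 bp downstream. Hes5, another Notch effector expressed in neural progenitors, had 0 peaks in the authors' gene list. The cyclin gene Ccnd2 had 1 peak of 45.4-fold, 554 bp upstream of its listed TSS but centred inside the gene body. Ccnd1 had 3 peaks, the strongest of 35.5-fold 94.7 kb upstream, with others of 24.8-fold at 2161 bp and 20.0-fold at 10.5 kb downstream of the TSS. The last of these was centred inside the gene body of LTO1.

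Bcl6 peaks lay mostly at promoters. The centre of 2171 peaks (56.0%) was within 1 kb of a TSS, and 246 of them lay within 1 kb of at least 2 TSSs. The peaks over the TSS of Bcl6 and Socs2 were promoter peaks. A further 424 peaks lay 1 to 5 kb away, 935 lay 5 to 50 kb away and 345 lay over 50 kb away, as those next to Klf9, Zbtb20 and Glce did.

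Random placement of peaks of the same widths on the same chromosomes put 3.32% ± 0.286 (SD over 10000 placements) of them within 1 kb of either end of a protein-coding gene, and never more than 4.44%. The observed share was 16.9 times the random one (two-sided permutation test, p = 0.0002, the smallest that the placements can give). The test is over positions in 1 pooled data set and not over replicate cultures. The random share counts both gene ends because the gene table gives no strand, so it lies above the share for TSSs alone.

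**Figure D1:**
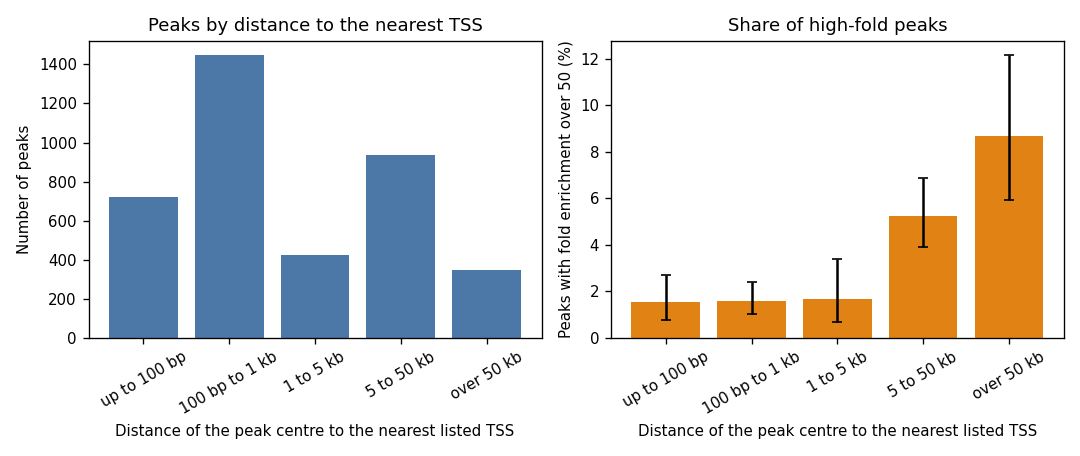
Left, number of Bcl6 peaks by distance of the peak centre to the nearest listed TSS. Right, percent of the peaks in each distance class with over 50-fold enrichment, with exact 95% binomial intervals; the share was 1.53% within 100 bp and 8.70% beyond 50 kb.

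The strongest enrichment was found away from promoters. Of the 25 peaks with the highest fold enrichment, 3 lay within 1 kb of a TSS, that of Socs2 among them, and 20 lay over 5 kb from one, among them the peaks near Klf9, Zbtb20 and Asb13. Enrichment over 50-fold was seen in 30 of 345 peaks over 50 kb from a TSS (8.70%, exact 95% interval 5.94 to 12.2%) and in 34 of 2171 promoter peaks, an odds ratio of 5.99 (Fisher's exact test chosen after the distances were seen, p = 7.85e-11).

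The shift over all peaks was small. Median enrichment was 20.3-fold for the 2171 promoter peaks (quartiles 16.4 and 25.6) and 21.9-fold for the 1704 others (quartiles 17.3 and 29.1). A peak away from promoters exceeded a promoter peak in 0.568 of pairs (two-sided permutation test over peaks, which are not independent replicates, p = 1e-05, the smallest that 100000 resamples can give). Ranked by the p-value score instead of the fold, the 2 classes did not differ detectably (0.509 of pairs, permutation p = 0.365).

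Wide peaks seldom had the highest folds. Across peaks, fold enrichment fell with width (Spearman's rho = −0.47, permutation p = 1e-04, the smallest that 10000 resamples can give, the same after adjustment over 6 relations), while tag count (rho = 0.86, same p) and the p-value score (rho = 0.42, same p) rose with width. Peaks at most 2 kb wide with high fold lay next to Klf9 (1470 bp, slightly above the median width of 1405 bp), Asb13 (1284 bp) and Zbtb20 (1092 bp). A peak of 7109 bp at Actb had 33.4-fold, still above the upper quartile of 27.2-fold over all peaks. Of the 25 peaks with the highest score 18 were over 2 kb wide, against 3 of the 25 with the highest fold. Over all peaks, 885 of 3878 were that wide, and these counts were not tested.

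**Figure D2:**
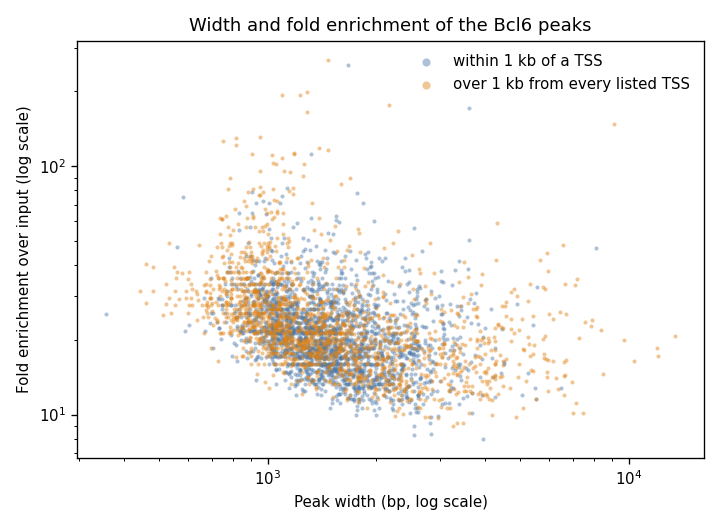
Fold enrichment over input against width, both on log scales, for the 3875 peaks with a listed gene; each point is a peak, coloured by whether its centre lies within 1 kb of a TSS. Peaks at most 2 kb wide reach the highest folds, up to 269-fold at 1470 bp.

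The screen was aimed at Bcl6 target genes. The authors' list tied 3875 peaks to 4540 genes, of which 4393 were among the 21887 protein-coding genes of the gene table (20.1%). Genes were grouped into 16 lists of signalling pathways, cell types and complexes fixed before the data were examined. In 9 of them more genes had a peak than in the background (Fisher's exact test per list, two-sided, Benjamini-Hochberg over the 16 lists), and no list had fewer at an adjusted p under 0.05. Housekeeping genes, the reference list, were among the 9, and only pluripotency genes had a higher odds ratio (6.99 against 5.99). The excess was thus not limited to signalling pathways or cell cycle genes, and the lists were not tested against each other.

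**Figure D3:**
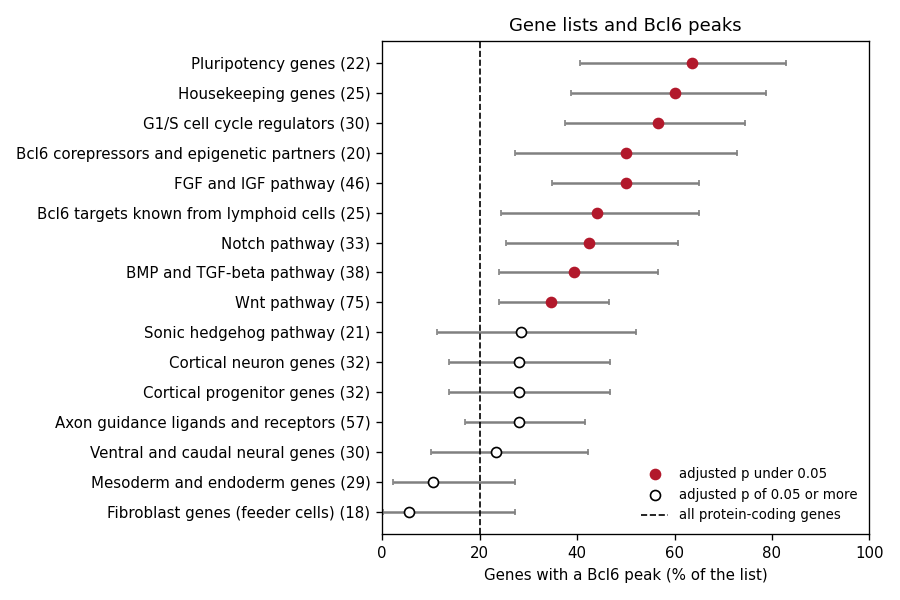
Percent of the genes in each fixed list that had a Bcl6 peak in the authors' gene list, with exact 95% binomial intervals (number of genes in brackets); filled points have an adjusted p under 0.05 and the dashed line marks the 20.1% of all protein-coding genes. Pluripotency genes are highest at 63.6% and fibroblast genes lowest at 5.56%.

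Of the 5 signalling pathways tested, 4 were among the enriched lists, and 2 of these, Wnt and BMP and TGF-beta, still passed without peaks over 2 kb wide, an alternative chosen after seeing the data. Both were lost with peaks within 5 kb or in the gene body, an alternative fixed beforehand (odds ratios 1.74 and 2.25, exact adjusted p = 0.0831 and 0.0677). Wnt was also lost under further alternatives given below. Genes of fibroblast and insulin-like growth factor (FGF and IGF) signalling had a peak in 23 of 46 cases (odds ratio 4.0, exact adjusted p = 5.6e-05; without peaks over 2 kb wide 1.78, exact adjusted p = 0.173). Igf1r, the IGF1 receptor gene, had 3 peaks, of 36.4-fold 1471 bp upstream, 23.6-fold at 566 bp and 20.5-fold at 176 kb downstream of the TSS. Igf2 had a peak of 25.6-fold, Igf2r had 1 of 26.6-fold 20 bp upstream of its TSS, and Fgf18 had a peak of 34.3-fold 1508 bp upstream.

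Notch pathway genes had a peak in 14 of 33 cases (odds ratio 2.94, exact adjusted p = 0.00791), 8 of them within 1 kb of the TSS. The ligand gene Dll4 had a peak of 25.6-fold 12.1 kb downstream of its TSS, and Dtx1 had 1 of 25.03-fold at 31.9 kb. Mib1, which encodes a ubiquitin ligase needed for ligand activity, was listed for a peak of 33.2-fold at 223 kb that was also the peak listed for the endoderm gene Gata6, 104 kb upstream of it.

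Genes of Wnt signalling had a peak in 26 of 75 cases (odds ratio 2.12, exact adjusted p = 0.00791). Porcn, whose product acylates Wnt ligands, had the strongest, of 78.1-fold 764 bp upstream of its TSS. The coactivator gene Bcl9 followed at 41.2-fold and 387 bp, Kremen1 at 41.2-fold and 168 bp, and the receptor gene Ryk at 38.4-fold and 108 kb, all upstream of the listed TSS. The Bcl9 peak was nevertheless centred inside the gene body. Genes of BMP and TGF-beta signalling had a peak in 15 of 38 cases (odds ratio 2.60, exact adjusted p = 0.0136), and 10 of these 15 had at least 2. Smad5 had a peak of 44.6-fold at its TSS. The inhibitory Smad7 had 4, the strongest of 42.6-fold at 127 kb. Id4 had 1 of 39.4-fold 15.8 kb upstream, and the strongest of the 3 peaks of Smad2 was 37.4-fold at 137 kb. Sonic hedgehog genes did not pass the test (6 of 21, odds ratio 1.59, exact adjusted p = 0.437). Its members with the strongest peaks were Ptch1 (37.2-fold), Shh (31.5-fold, 743 kb upstream), Gli3 (28.4-fold) and Gli2 (25.3-fold).

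Cell cycle genes were enriched. Regulators of the G1/S transition had a peak in 17 of 30 cases (odds ratio 5.22, exact adjusted p = 5.6e-05), 11 of them within 1 kb of the TSS. Cdk6, the partner kinase of D cyclins, had a peak of 55.2-fold, 1093 bp upstream of the listed TSS but centred inside the gene body. Ccnd2 had 1 of 45.4-fold and Ccne1 1 of 42.7-fold 4733 bp upstream. Genes known as Bcl6 targets in lymphoid cells had a peak in 11 of 25 cases (odds ratio 3.13, exact adjusted p = 0.0167), among them Socs2, Bcl6, Ccnd2 and the cytokine feedback gene Cish (63.3-fold, 746 bp from the TSS). Bcl6 corepressors and chromatin partners had a peak in 10 of 20 cases (odds ratio 3.99, exact adjusted p = 0.00791). Mta3 had a peak of 43.1-fold 28.6 kb upstream, Tbl1xr1 1 of 42.7-fold 460 bp upstream and Ctbp2 1 of 34.0-fold. Neither the lymphoid targets nor the corepressors passed without peaks over 2 kb wide.

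Lists of neural identity did not pass the main test. Cortical progenitor genes had a peak in 9 of 32 cases (odds ratio 1.56, exact adjusted p = 0.307). Sox2 had 5 peaks, of which 3 formed a cluster 95.1 to 110 kb downstream of its TSS, with 55.9-fold at the strongest. Emx1 had a peak of 37.4-fold at its TSS, Sox9 1 of 33.2-fold at 350 bp, and Pax6 1 of 29.7-fold at 1164 bp. Cortical neuron genes gave the same count, 9 of 32, with peaks at Pou3f2 (41.4-fold, 347 kb upstream), Elavl3 (35.5-fold) and Elavl4 (29.6-fold) among them. Axon guidance genes had a peak in 16 of 57 cases (odds ratio 1.56, exact adjusted p = 0.218), and the odds ratio was 1.52 with domain length in the model. Random placements gave 22.9 axon guidance genes against 13 observed (0.567 times, permutation adjusted p = 0.0024). The placements were even along each chromosome, while the observed peaks lay mostly at promoters. This value therefore cannot show that Bcl6 avoided axon guidance genes. The strongest peaks were those of Efnb2 (47.3-fold), Plxnc1 (37.8-fold), and Ephb3 and Plxnd1 (37.4-fold each).

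Markers of other cell types fell on both sides of the background. Pluripotency genes had the highest share of all lists in the main test, 14 of 22 (63.6%, exact 95% interval 40.7 to 82.8%, odds ratio 6.99, exact adjusted p = 5.6e-05), and 2 of the 14 had a peak within 1 kb of the TSS. With peaks within 1 kb alone, an alternative chosen after seeing the data, their odds ratio was 0.828. With peaks within 5 kb or in the gene body, 11 of the 22 had a peak, below the 14 of 25 housekeeping genes. Zfp42 had 4 peaks, of 37.4-fold 13.9 kb upstream and of 15.5- to 25.5-fold downstream of its TSS, the widest of them 6726 bp with a score of 625. Tbx3 had 4, up to 31.5-fold, Prdm14 had 1 of 30.6-fold at 41.9 kb, and Esrrb had 3, up to 29.3-fold. Ventral and caudal neural genes had a peak in 7 of 30 cases (odds ratio 1.21, exact adjusted p = 0.649), none within 1 kb of the TSS. Among them were Lhx8 (78.8-fold, 51.2 kb upstream), Pax2 (61.1-fold, 59.5 kb upstream) and Hoxb1 (26.4-fold). Mesoderm and endoderm genes had a peak in 3 of 29 cases (odds ratio 0.459, exact adjusted p = 0.307), which were Pax3 (33.7-fold), Gata6 (33.2-fold) and Snai1 (18.1-fold). With peaks within 5 kb or in the gene body alone, 0 of the 29 had a peak, fewer than in the background (odds ratio 0.0933, exact adjusted p = 0.0333). Fibroblast genes, included because ES cells had been kept on feeder fibroblasts, had 1 of 18, Loxl1 at 14.4-fold (odds ratio 0.234, exact adjusted p = 0.150).

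Housekeeping genes, taken as a reference, had a peak in 15 of 25 cases (odds ratio 5.99, exact adjusted p = 5.6e-05). Their peaks were wide, with 19 of 27 over 2 kb, and 13 of the 25 genes had a peak over 2 kb wide. Besides the peak at Actb, the cyclophilin gene Ppia had 1 of 5664 bp and 41.9-fold. The stronger of the 2 peaks listed for Hsp90ab1, of 6645 bp and 33.4-fold, was centred 6300 bp from its TSS and beyond the end of the gene. The transferrin receptor gene Tfrc differed, with a narrow peak of 1021 bp and 65.4-fold 97.8 kb upstream.

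Without the 885 peaks over 2 kb wide, an alternative chosen after seeing the data, 4 of the 9 lists (Wnt, BMP and TGF-beta, G1/S and pluripotency) still passed, and the odds ratios of Notch (2.19, exact adjusted p = 0.133), FGF and IGF (1.78, 0.173), lymphoid targets (1.96, 0.210), corepressors (2.72, 0.115) and housekeeping genes (1.96, 0.210) did not. The Wnt call was also lost with random placements (1.31 times the expected count, permutation adjusted p = 0.330), with the 1939 peaks of the highest scores (odds ratio 1.57, exact adjusted p = 0.302) and with peaks within 5 kb or in the gene body (1.74, 0.0831). BMP and TGF-beta was lost with the last (2.25, 0.0677) and corepressors with random placements (1.65 times, permutation adjusted p = 0.272). That alternative also changed the assignment, to the nearest gene end. It left 18 Wnt and 7 corepressor genes with a peak, against 26 and 10 in the main test. With only peaks within 1 kb of a TSS 3 lists passed (G1/S, lymphoid targets and housekeeping), and with only peaks over 5 kb away, Wnt (1.61, exact adjusted p = 0.243), G1/S (2.09, 0.262) and lymphoid targets (0.908, 1) did not, while cortical neuron genes passed (7 of 32, odds ratio 2.93, exact adjusted p = 0.0493). Against all annotated genes, Sonic hedgehog (4.08, exact adjusted p = 0.0105) and cortical progenitor and cortical neuron genes (3.99 each, 0.00203) passed as well. So did axon guidance (3.98, exact adjusted p = 4.29e-05) and ventral and caudal neural genes (3.10, 0.0169). That background adds largely non-coding genes that are seldom listed, which raised the odds ratio of every list. These added calls therefore say little about the lists themselves.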

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

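The comparisons by gene left out 3 peaks for which the authors' gene list names no gene. Each was flagged because it is a signal in data that those comparisons do not use. A peak on chromosome 1 from 122607174 to 122607828 had 64.6-fold enrichment, 77 tags and a score of 247, which places it among the stronger peaks. Another on chromosome 1, from 113970543 to 113971123, had 27.9-fold enrichment and 28 tags. The third lay on unplaced sequence of chromosome 4 and had 15.6-fold enrichment and 73 tags over 1548 bp. No explanation was tested for these peaks.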

How the results depend on the processing

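No paired analysis was possible because the authors pooled the libraries of each group and the files hold no value per replicate, and for the same reason no library was left out. The motif test and its 4 alternatives were not run. The promoter share kept its direction and its side of the threshold under all 7 alternatives, at 55.9 to 66.9% and 4.93 to 17.8 times the random share. The excess in fold away from promoters kept its direction under all 4 alternatives (0.509 to 0.618 of pairs), but passed the threshold in 3 of them and not with the score (0.509). The number of peaks was 3840 with an FDR of at most 5%, and 1939 with a score at or above the median, by construction. The 9 enriched lists became 14 against all annotated genes, where the added genes are largely non-coding and seldom listed. Among alternatives chosen after seeing the data, 3 lists were enriched with peaks within 1 kb of a TSS and 4 without peaks over 2 kb wide. The other 7 alternatives gave 7 to 9. Odds ratios that crossed 1 were those of ventral and caudal neural genes with peaks within 5 kb or in the gene body (0.190), with the 1939 highest scores (0.913) and within 1 kb (0.136), and those of cortical neuron (0.711) and axon guidance genes (0.567, permutation adjusted p = 0.0024) with random placements, where the value is observed over expected. The placements used the nearest gene end, so the null and the assignment changed together. They were also even along each chromosome, unlike the observed peaks, so values under 1 there do not show that Bcl6 avoided a list. Cortical neuron and axon guidance genes then had 7 and 13 genes with a peak, against 9 and 16 in the main test. With peaks within 1 kb, cortical progenitor (0.857), cortical neuron (0.267) and pluripotency genes (0.828) crossed 1 too. With peaks over 5 kb away, lymphoid targets (0.908) and mesoderm and endoderm genes (1.21) did, the latter also against all annotated genes (1.17). The cause was not tested. What depth limits was not tested, and the weakest peaks held 20 tags.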

Other observations

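The tests in this part were chosen after the results were seen. The families below were chosen after peaks of some of their members were seen, so their counts are descriptive. Of 85 ribosomal protein genes, 65 had a peak (76.5%, against 20.1% of all protein-coding genes), and 48 had a peak over 2 kb wide. Among heterogeneous nuclear ribonucleoprotein (Hnrnp) genes 14 of 21 had a peak, among Srsf splicing factor genes 8 of 11, and among genes with an Eif symbol, which hold translation initiation factors and some of their regulators, 25 of 56. Socs genes with Cish had peaks in 6 of 8 cases and Klf genes in 10 of 17. Fox genes had 18 of 44. Zfp genes had 77 of 397. Hox genes (4 of 39), protocadherin genes (5 of 69), olfactory receptor genes (9 of 1110), vomeronasal receptor genes (2 of 353) and keratin genes (1 of 53) had few.

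Non-coding genes carried some of the largest peaks. Malat1, a nuclear long non-coding RNA, lay under a peak of 11974 bp with 1061 tags and 18.6-fold enrichment, and Neat1 under 1 of 6181 bp. Of 17 Snhg genes, hosts of small nucleolar RNAs, 12 were overlapped by a peak, against 540 of 12710 other long non-coding genes. The set was chosen after its peaks were seen, so the counts are descriptive. Snhg3 had 25-fold over 5425 bp and Snhg7 23.9-fold over 7930 bp. A single peak of 5978 bp and 38.0-fold on chromosome 7, from 3217533 to 3223510, covered all 9 genes of the Mir290 to Mir295 cluster, microRNAs characteristic of ES cells. No peak overlapped the neural microRNA genes Mir9-1, Mir9-2, Mir9-3, Mir124a-1, Mir124a-2 or Mir124a-3, nor Mir302a, Mir302b, Mir302c or Mir302d, a second cluster typical of pluripotent cells. The peak with the highest tag count, 1158 tags at 13.9-fold on chromosome 17 from 39842846 to 39847108, overlapped Rn18s-rs5, a ribosomal RNA related sequence.

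Some wide peaks lay past the ends of genes. Eef1a1 had a peak of 6461 bp centred 3369 bp beyond its end, Rpsa 1 of 4827 bp at 1789 bp beyond, and H3f3b 1 of 3923 bp at 2715 bp beyond. Ribosomal protein genes had a peak centred 1 to 5 kb beyond the end in 19 cases and 1 to 5 kb upstream of the TSS in 5. Of the 1704 peaks over 1 kb from a TSS, 235 lay 1 to 5 kb beyond the end of a listed gene and 164 lay 1 to 5 kb upstream of a TSS (exact binomial test, p = 0.000444). A peak listed for 2 genes can count on both sides, which the test takes as exclusive and equally likely. The basal domains of the gene list also reach further upstream than downstream of a TSS. Peaks over 2 kb wide lay beyond an end more often than narrower ones (22.0% against 10.8%, Fisher's exact test, odds ratio 2.32, p = 1.26e-08), but they were also more often upstream (13.4% against 8.25%), and the ratio of the 2 sides did not differ detectably with width (p = 0.301).

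Whether strength of enrichment sets the width stays open, since width fell with fold (rho = −0.47) and rose with the p-value score (rho = 0.42). A signal that goes with heavy transcription may account for wide peaks, as 52% of the housekeeping genes (13 of 25) had a peak over 2 kb wide against 5.08% of the other protein-coding genes (Fisher's exact test, odds ratio 20.3, p = 4.66e-11). The list was fixed before the data were examined, but the test was chosen after its wide peaks were seen. Such peaks were not limited to housekeeping genes, with 8 of 22 pluripotency, 13 of 46 FGF and IGF and 0 of 29 mesoderm and endoderm genes. Transcription was not measured in these files. Whether Bcl6 bound genes with wide peaks or the precipitation gave an unspecific signal there stays open, and no biological explanation was tested.

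Pluripotency genes often had a peak although the culture was at differentiation day 12. Large regulatory domains are argued against as the whole cause, because the odds ratio was 7.47 with domain length in the model and the list still passed the threshold of 0.05. Without peaks over 2 kb wide the odds ratio was 3.49 (9 of 22, exact adjusted p = 0.0312), down from 6.99. That of housekeeping genes was 1.96 (7 of 25, exact adjusted p = 0.210). Whether the wide signal at heavily transcribed genes is the cause cannot be decided this way. The cut leaves narrower peaks next to wide ones, such as that of 1665 bp at Zfp42 beside that of 6726 bp. Whether undifferentiated cells in the culture or binding in the progenitors themselves gave the peaks at pluripotency genes was not tested, as the pooled peaks hold no measure of expression or of cell type.

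The highest folds lay mostly far from promoters at sites at most 2 kb wide, such as those near Klf9, Zbtb20 and, chosen after its value was seen, the kinase gene Pim1 (166-fold, 91.3 kb upstream). The excess of far peaks at the top was not limited to a ranking by fold. Among the 120 peaks with the highest score, as many as have over 50-fold, 17 of the 345 peaks over 50 kb from a TSS appeared and 29 of the 2171 promoter peaks (Fisher's exact test, odds ratio 3.83, p = 5.75e-05). The score comes from the same tags as the fold and is no independent check. Over all peaks it did not separate promoter peaks from the others detectably (0.509 of pairs, permutation p = 0.365). A thin input as the whole cause is argued against by the ChIP tags. Among the 120 peaks with the most tags for their width, ranked within 20 classes of width, 25 of the peaks over 50 kb from a TSS appeared and 42 of the promoter peaks (Fisher's exact test, odds ratio 3.96, p = 8.02e-07). As a hypothesis, these sites may be where Bcl6 contacts its own DNA motif, which is close to that of the STAT proteins known to drive Pim1. The sequence under the peaks was not analysed here, so this stays open.

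Chromosome X had 49 peaks, 5.07 per 100 protein-coding genes, against 18.5 on the autosomes (exact binomial test, p = 2.00e-29). The test takes peaks as independent and genes as equal targets. The cause was not tested, and the number of X copies in these cells was not examined. The FDR of the authors' table reached 100% at the Socs2 peak and exceeded 5% at 38 peaks, all with a score of at least 490. Multiplied by rank, the column corresponds to 1 peak called with ChIP and input exchanged at the score of Socs2, 11 among the first 1939 peaks and 101 over all 3878.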
